A study of Mus musculus with 13 samples.

How the data were processed

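RNA-seq of mesenchymal stromal cells sorted from bone marrow and compact bone of C57BL/6 mice was deposited as 1 table of FPKM values for 13 libraries, 3 healthy, 6 pre-leukemic and 4 recovered. Per the labels' protocols, polyadenylated RNA was turned into cDNA by a published method and made into libraries with a Nextera XT kit. The submitters' processing notes name bcl2fastq, TopHat, Cufflinks 2.2.1, Cuffnorm and the mm10 build. The FPKM values were made by the authors with these tools, and the library-size method of Cuffnorm and the gene annotation are not given in the sources used here. Where a few genes hold much of the RNA, that method can shift a library as a whole.

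The table held 33433 gene entries, of which 32082 had a symbol found in the reference annotation of GRCm38 (mm10), the source of the coordinates. No read counts were used. Depth was estimated from the steps between low FPKM values of 2825 genes with a single transcript of at least 800 bp, within a tolerance of 0.06 on the log2 scale, and is approximate. The value of 3 reads on 1 kb was 0.936 to 1.153 FPKM in healthy, 0.495 to 0.71 in pre-leukemic and 1.046 to 1.925 in recovered libraries, which covers counting error only.

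Pairs of libraries of the same group were compared by a chi-square of their estimated reads. Healthy 1 and 3 differed by about the sampling noise (correlation across genes 0.983, others 0.739 to 0.934), and their mean was used as 1 sample. The planned fit held 13 separate libraries, so the fit used here, with 12 samples and 9 residual degrees of freedom, departs from it, and counts of the planned fit are given beside the main ones.

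Values were tested on log2(FPKM + 1) with limma 3.58.1 (lmFit, eBayes with trend) in R 4.3.3, all 3 groups in 1 fit, for 13118 genes with at least 1 FPKM in at least 3 libraries. Adjusted p-values are Benjamini-Hochberg values of limma, and calls are those under 0.05. The planned fit, the 34 gene lists, the rule for named genes and the alternatives not said to be added were set before the data were examined. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation, its p adjusted likewise, with fry beside it. A list needed 5 tested members. Where 1 pair of counts of higher and lower members is given, the counts adjusted over the list alone were the same. Unless a second value is given, a list call also held with an estimated correlation.

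Among genes called with at least 1 FPKM in every library of the higher group, the 12 largest rises and the 12 largest falls of each comparison were taken, leaving out gene models without a standard symbol. Added to these were up to 4 members of each list with the smallest p, the 10 genes called in opposite directions with the largest smaller change, and 7 genes named in advance (Cxcl12, Kitl, Lepr, Pdgfra, Pdgfrb, Ptprc and Pecam1). Members named because a count was 5 or fewer were chosen after their values were seen. Some genes taken by the rule are not reported here.

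Alternatives were quantile normalization, the TPM scale, a pseudocount of 0.1, no filter on low values, a mean of at least 5 FPKM, only the groups compared, arrayWeights, robust eBayes, replicate number as a block and leaving out each library. The block was fitted to the 13 separate libraries, as the mean of healthy 1 and 3 has no single number. Scaling to the sum without immunoglobulin genes and separate healthy libraries without the block were chosen after seeing the data. A range after an adjusted p is over all of these.

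The steps were tested on simulated data with 100 changed genes per size among 13118. In pre-leukemic versus healthy 35% of genes changed by a log2 of 2 and 73% of those changed by 3 were recovered, in recovered versus pre-leukemic 53 and 92%, and in recovered versus healthy 29 and 71%. Of unchanged genes 8, 6 and 3 were called. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 made the summaries and plots.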

Results

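RNA-seq measured gene expression in mesenchymal stromal cells (MSCs), connective-tissue cells that make matrix and signals for blood-forming cells, of C57BL/6 mice. The 13 libraries were 3 healthy, 6 pre-leukemic and 4 recovered, the last matching the protocol's pre-leukemic mice that received MSCs. Each library was made from polyadenylated RNA of cells sorted out of marrow and compact bone, and its values are FPKM, fragments scaled by gene length and library depth. The sort's surface markers and whether replicates came from separate animals are not given in the sources used here, so p-values measure the spread between these samples.

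Healthy libraries 1 and 3 differed by about the sampling noise. Over 289 genes with 100 to 1000 estimated reads, the chi-square per gene was 1.03 (p = 0.345), and over 357 genes with 10 to 100 reads it was 1.27 (p = 0.000315). The other 23 pairs of libraries from the same group reached at least 19.6 and 9.84. Both libraries were therefore averaged and counted as 1 sample. Without healthy 2 a single healthy sample is left, assumed to vary like the other groups. All levels below are means ± SD in FPKM over 2 healthy, 6 pre-leukemic and 4 recovered samples, and changes are on the log2(FPKM + 1) scale ± SE, which understates changes of genes with low values. Changes stand in parentheses after a gene, followed by limma's adjusted p, which stands alone where a group was listed at 0. Counts called unadjusted are those at an unadjusted p under 0.05.

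The depth, estimated from the steps between low values, put 1 read on 1 kb at 0.312 to 0.384 FPKM in healthy, 0.165 to 0.237 in pre-leukemic and 0.349 to 0.642 in recovered libraries. Immunoglobulin genes held 54.9 to 80.5% of the summed FPKM of the pre-leukemic libraries and at most 0.134% in the others. Mitochondrial ribosomal RNA was 0.03 to 0.09% of the sum in pre-leukemic and 0.9 to 1.23% in the other libraries. The first principal component, 52.2% of the variance, separated the pre-leukemic libraries from the rest, and the second, 10.1%, set recovered 3 (-130.6) apart.

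Cxcl12, the chemokine that retains blood stem cells in marrow (GRCm38 chromosome 6, 117168535 to 117181367), was at 439.3 ± 97.1 FPKM in healthy, 44.4 ± 41 in pre-leukemic and 732.9 ± 176 in recovered samples. Lepr, a receptor that marks marrow stromal cells (chromosome 4, 101717404 to 101815352), was at 24.4 ± 2.59, 1.68 ± 2.85 and 34.1 ± 21.4. The platelet-derived growth factor receptors Pdgfra and Pdgfrb were at 39.2 ± 6.93 and 53.9 ± 4.58 in healthy, 4.43 ± 3.3 and 1.21 ± 0.79 in pre-leukemic, and 19.8 ± 5.75 and 23.6 ± 10.5 in recovered samples. Ptprc, which encodes the leukocyte antigen CD45 (chromosome 1, 138062861 to 138175708), ran the other way, at 0.5 ± 0.594, 128.7 ± 28.3 and 4.62 ± 7.89. Kitl, the ligand of the stem cell receptor Kit, was at 3 ± 3.05, 0.664 ± 0.844 and 7.42 ± 4.84, and the endothelial adhesion gene Pecam1 at 0.79 ± 0.294, 2.24 ± 1.79 and 0.209 ± 0.0475. Cxcl12 was at 28.5 and Kitl at 0.404 without pre-leukemic 1, Lepr at 0.539 without pre-leukemic 5 and Ptprc at 0.686 without recovered 2.

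**Figure D1:**
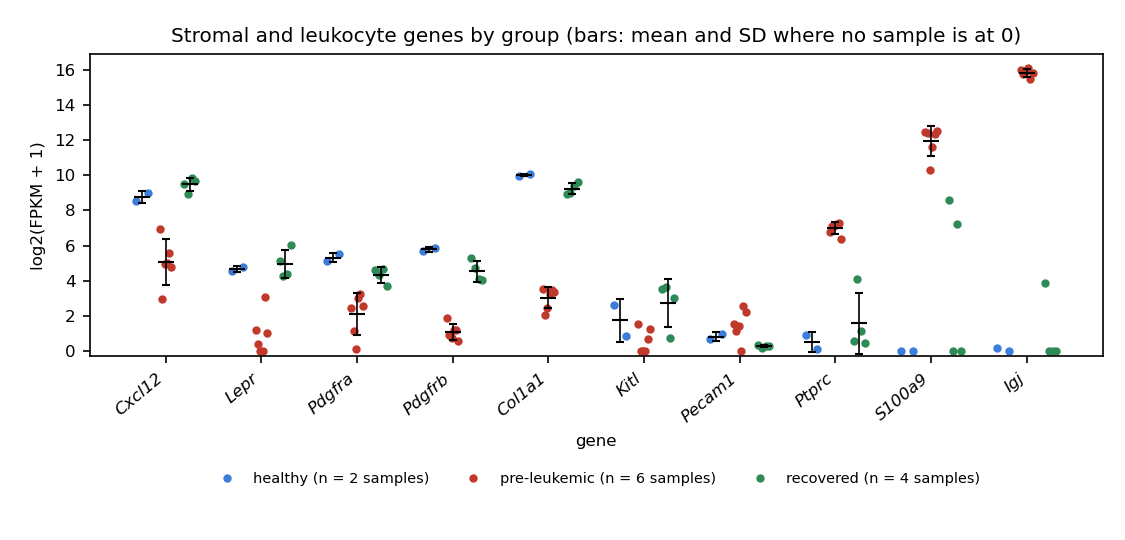
Stromal and leukocyte genes in each sample, by group, as log2(FPKM + 1) on the vertical axis. Points are samples (2 healthy, with healthy 1 and 3 averaged, 6 pre-leukemic and 4 recovered), and bars give the mean and SD of that log value where no sample of the group is at 0. Col1a1 averaged 1041 ± 40.7, 7.71 ± 3.05 and 612 ± 138 FPKM in the 3 groups.

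How cells sorted as MSCs from pre-leukemic mice differed from those of healthy mice was the first comparison. Genes of bone, cartilage and matrix fell and immunoglobulin genes and leukocyte markers rose. Col1a1, the main collagen chain of bone (chromosome 11, 94936224 to 94953042), fell (-7.0 ± 0.42, 8.38e-08), as did Ibsp, a bone matrix sialoprotein, from 1392 ± 58.3 to 2.15 ± 2.92 (-9.32 ± 0.75, 1.27e-06), or to 1.19 without pre-leukemic 5. Igj, the immunoglobulin joining chain now named Jchain (chromosome 5, 88519809 to 88527891), rose from 0.0658 ± 0.093 to 58550 ± 8580 (15.73 ± 0.77, 7.24e-09). S100a9, a calcium-binding protein of neutrophils, was listed at 0 in healthy samples and averaged 4461 ± 1860 FPKM in pre-leukemic samples (0.000213). By limma, 1858 genes were higher and 1725 lower among 13118 tested.

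Chad, a cartilage protein, was among the genes with the largest falls, from 2446 ± 17.9 to 1.4 ± 1.87 (-10.34 ± 0.63, 9.73e-08). Col12a1, a fibril-associated collagen, fell from 963.3 ± 92.1 to 1.97 ± 3.96 (-9.03 ± 0.75, 1.55e-06). The secreted chaperone Clu fell from 1354 ± 263 to 3.02 ± 3.41 (-8.84 ± 0.70, 1.2e-06), and the collagenase Mmp13 from 742.1 ± 116 to 1.31 ± 2.02 (-8.74 ± 0.68, 9.71e-07). Cytl1, a secreted protein of cartilage, averaged 553.2 ± 144 FPKM in healthy samples and was listed at 0 in pre-leukemic samples (0.000158). Fmod, a collagen-binding proteoglycan, fell (-8.61 ± 0.69, 1.2e-06), and so did Angptl7 (-7.66 ± 0.78, 8.46e-06), the protease inhibitor Timp1 (-7.49 ± 0.68, 3.27e-06), the cartilage matrix protein Comp (-7.47 ± 0.53, 4.79e-07) and Anxa8 (-7.08 ± 0.79, 1.91e-05). Without pre-leukemic 5, 4 and 1 the pre-leukemic means of Chad, Col12a1 and Mmp13 were 0.831, 0.364 and 0.685.

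Immunoglobulin genes led the rises: 33 of the 68 tested passed, each of them higher. Igkv5-39, a kappa variable gene, averaged 82250 ± 32600 FPKM in pre-leukemic samples (6.22e-13), and the heavy chain constant gene Ighg2c 50090 ± 27100 (6.14e-10). Both were listed at 0 in healthy samples. Ighg2b was at 41590 ± 27500 (14.65 ± 0.64, 2.94e-09), Iglv1 at 24150 ± 15000 (2.06e-09), Ighj4 at 10820 ± 4600 (1.9e-10), Ighv3-6 at 2468 ± 1050 (1.2e-08) and Igkv4-57 at 4109 ± 5160 (0.000204), or 2402 without pre-leukemic 4. Igkv5-48 (0.00351), Igkv12-46 (0.00248) and Igkv4-72 (0.00282) also passed. Without healthy 2 the adjusted p, with its range over the alternatives, was above 0.05 for Igkv5-48 (0.0644, range 1.62e-07 to 0.0644), Igkv12-46 (0.0524, 2.78e-09 to 0.0524) and Igkv4-72 (0.0558, 1.3e-08 to 0.0558). Near-identical variable genes share reads, so values of single immunoglobulin genes are uncertain. Igkc, the kappa constant gene, was listed at 0 in pre-leukemic 1 and 2 and at 966145 to 1668370 FPKM in pre-leukemic 3 to 6. These 0 values may be failed estimates, since Igkv5-39 was at 54500 and 93200 FPKM in pre-leukemic 1 and 2. Immunoglobulin genes held 54.9 and 55.3% of the summed FPKM there, against 70.7 to 80.5% in the others.

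Stromal identity and niche genes fell. The 18 tested genes of mesenchymal identity were 1 higher, 11 lower and 6 neither, 1 and 12 adjusted over the list alone (camera adjusted p = 1.72e-06). Cxcl12 (-3.72 ± 0.69, 0.0011), Lepr (-3.71 ± 0.76, 0.00225), Pdgfrb (-4.70 ± 0.52, 1.73e-05), the transcription factor genes Prrx1 (-3.90 ± 0.53, 9.66e-05) and Ebf1 (-3.76 ± 0.52, 0.000103) passed. Pdgfra passed (-3.22 ± 0.73, 0.00459), but not without healthy 2 (0.0762, range 8.89e-05 to 0.0762). The 30 haematopoietic niche factors were 0 higher, 18 lower and 12 neither (adjusted p = 6.28e-08). They included the growth factor Igf2 (-6.89 ± 0.71, 8.99e-06), Gas6, a ligand of TAM receptors, (-5.26 ± 0.59, 1.92e-05), and the Notch ligand Jag1 (-4.54 ± 0.56, 4.25e-05). Kitl did not pass (-1.16 ± 0.78, 0.288), nor did Pecam1 (0.66 ± 0.56, 0.417). The pan-leukocyte median change was 4.74.

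The skeletal lineages and their matrix showed the largest list falls. The 22 osteoblast genes divided into 0 higher, 21 lower and 1 neither (adjusted p = 1.09e-16). Col1a2 (-6.36 ± 0.41, 1.37e-07) and the bone phosphoprotein Spp1 (-6.44 ± 0.52, 1.26e-06) passed. The 18 chondrocyte genes held 0 higher, 15 lower and 3 neither, 0 and 16 adjusted over the list alone (adjusted p = 2.8e-13). Sox9, the transcription factor of cartilage formation, fell from 42.3 ± 6.62 to 0.121 ± 0.161 (-5.27 ± 0.45, 1.94e-06), or to 0.0662 without pre-leukemic 1, and Ucma, a cartilage matrix gene, was at 29.2 ± 19.4 FPKM in healthy samples and listed at 0 in pre-leukemic samples (1.74e-06). The 52 extracellular matrix genes were 0 higher, 49 lower and 3 neither, 0 and 50 adjusted over the list alone (adjusted p = 1.49e-33). Ctgf, a matricellular protein induced by TGF-beta, fell (-5.74 ± 0.41, 4.79e-07). In the same 6 libraries, all above both healthy samples, Ptprc rose by 6.46 ± 0.78 (adjusted p = 3.44e-05).

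Signalling and support lists fell too. The 26 TGF-beta genes held 0 higher, 16 lower and 10 neither, 0 and 17 adjusted over the list alone (adjusted p = 2e-09), among them the transcription inhibitor Id3 (-4.49 ± 0.51, 2.19e-05). For Wnt signalling the 26 genes gave 2 higher, 18 lower and 6 neither (adjusted p = 4.82e-08). The receptor Fzd1 (-5.07 ± 0.51, 7.41e-06) and the secreted modulator Sfrp2 (-6.33 ± 0.68, 1.27e-05) passed. The 17 MAPK output genes gave 0 higher, 9 lower and 8 neither, 0 and 11 adjusted over the list alone (adjusted p = 1.19e-05), and Ier3 fell (-4.70 ± 0.36, 9.71e-07). Smooth muscle and pericyte markers were 0 higher, 8 lower and 4 neither, 0 and 9 adjusted over the list alone (adjusted p = 2.83e-06). Rgs5 and Acta2, a pericyte regulator and smooth muscle actin, were at 57.5 ± 14.6 and 30.9 ± 0.89 FPKM in healthy samples and listed at 0 in pre-leukemic samples (adjusted p = 2.84e-06 and 7.09e-05). The 16 complement genes were 1 higher, 10 lower and 5 neither (adjusted p = 2.83e-06). The protease C1s1 (-3.31 ± 0.38, 2.39e-05) passed. The 32 macrophage-directed signals, of which 17 also stand in other lists, were 5 higher, 18 lower and 9 neither (adjusted p = 4.28e-05). Falls were those of the galactose-binding lectin Lgals3 (-4.27 ± 0.36, 1.61e-06), Tnfaip6 (-5.85 ± 0.56, 5e-06) and Thbs1, a matrix glycoprotein, (-5.55 ± 0.55, 6.85e-06). Immediate early genes were 0 higher, 14 lower and 12 neither, 1 and 14 adjusted over the list alone (adjusted p = 1.18e-07, p = 0.0546 with estimated correlation). Egr1 (-2.41 ± 0.20, 1.61e-06) passed. The pan-leukocyte median beside these lists was 4.74.

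Interferon and antigen presentation lists rose in libraries where 16 of 16 pan-leukocyte markers were higher, with a median of 4.74, and Igj rose by 15.73 ± 0.77. Interferon response genes were 30 higher, 1 lower and 10 neither, 33 and 1 adjusted over the list alone (adjusted p = 4.91e-12). The interferon regulator Irf7 rose (5.05 ± 0.48, 5e-06), with the proteasome subunit Psmb8 (4.35 ± 0.43, 6.79e-06) and the antiviral gene Mx1, listed at 0 in healthy and 25.9 ± 5.75 FPKM in pre-leukemic samples (5.03e-06). Antigen presentation genes were 18 higher, 0 lower and 2 neither (adjusted p = 2.18e-13). Cd74, the class II invariant chain, (8.38 ± 0.40, 6.63e-09), B2m (3.42 ± 0.18, 1.77e-08) and the class I gene H2-K1 (3.81 ± 0.23, 9.65e-08) passed. Inflammatory cytokines and chemokines did not pass as a list and held 10 higher, 11 lower and 18 neither, 12 and 12 adjusted over the list alone (adjusted p = 0.601). The chemokines Cxcl14 (-5.70 ± 0.69, 3.72e-05) and Cxcl1 from 2191 ± 181 to 50.2 ± 43.6 (-5.96 ± 0.77, 5.99e-05) fell. Tnfaip3, an inhibitor of NF-kappa-B, rose (4.78 ± 0.58, 3.8e-05), as did the chemokine Ccl5, listed at 0 in healthy and 85.9 ± 32 FPKM in pre-leukemic samples (5.66e-06). The unfolded protein response genes were 10 higher, 3 lower and 12 neither (adjusted p = 0.00661, p = 0.133 with estimated correlation). On the TPM scale the list had adjusted p = 0.113 (range 0.00225 to 0.113). Xbp1, which drives secretory capacity, rose (3.03 ± 0.37, 3.55e-05), as did Edem1 (4.84 ± 0.43, 2.67e-06) and Chac1 (4.50 ± 0.55, 3.8e-05). The chaperone Hsp90b1 rose (1.99 ± 0.30, 0.000239), though not on the TPM scale (0.659, range 2.15e-05 to 0.659).

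Pan-leukocyte, T and NK cell, monocyte and neutrophil markers rose. The 16 pan-leukocyte markers were 16 higher, 0 lower and 0 neither (adjusted p = 4.91e-12). Rac2, a GTPase of blood cells, (5.59 ± 0.55, 5.82e-06), the integrin Itgb2 (6.53 ± 0.67, 8.76e-06), Lcp1 (5.34 ± 0.56, 9.97e-06) and Plek (4.40 ± 0.49, 1.77e-05) passed. T and NK cell markers were 13 higher, 0 lower and 2 neither (adjusted p = 1.35e-10). Cd3d, a T cell receptor component, was listed at 0 in healthy and 51.6 ± 9.48 FPKM in pre-leukemic samples (8.87e-07), and Zap70 (4.63 ± 0.50, 1.48e-05) and Il2rb (4.36 ± 0.49, 1.91e-05) rose. Monocyte and macrophage markers were 5 higher, 0 lower and 7 neither, 6 and 0 adjusted over the list alone (adjusted p = 0.000493). The higher were Ctss (8.22 ± 0.59, 4.79e-07), Ly6c2 (9.10 ± 0.93, 8.44e-06), Lyz2 (6.55 ± 0.82, 4.57e-05), Mpeg1 (5.62 ± 0.66, 2.66e-05) and Ccr2, listed at 0 in healthy samples (1.03e-05). Neutrophil and granulocyte precursor markers were 13 higher, 0 lower and 7 neither, 15 and 0 adjusted over the list alone (adjusted p = 3.96e-07, p = 0.0795 with estimated correlation). S100a8 rose (9.47 ± 1.10, 2.59e-05). Ngp, Lcn2 and Retnlg, listed at 0 in healthy samples, averaged 1272 ± 732, 597.6 ± 301 and 209.1 ± 159 FPKM (adjusted p = 3.86e-05, 1.27e-06 and 1.17e-05).

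B cell markers went both ways, and 3 of 8 erythroid markers were lower. The 15 B cell markers were 8 higher, 4 lower and 3 neither and did not pass as a list (adjusted p = 0.077). The list passed without pre-leukemic 5 (0.0402, range 0.0156 to 0.155), under quantile normalization (0.0352) and on the TPM scale (0.0156). Iglc2 (8.09 ± 0.82, 8.18e-06) and Ighm (8.06 ± 0.95, 2.81e-05) rose. The 4 lower were the pre-B receptor genes Igll1 and Vpreb2, listed at 0 in pre-leukemic samples against 88.3 ± 1.15 and 8.28 ± 1.91 FPKM in healthy samples (adjusted p = 2.68e-05 and 0.00406), Vpreb1 (-5.01 ± 0.83, 0.000463) and the B lineage factor Pax5 (-2.09 ± 0.40, 0.00129). Erythroid markers were 0 higher, 3 lower and 5 neither (adjusted p = 0.00276, p = 0.0755 with estimated correlation). The lower were the globins Hba-a2 from 16.9 ± 0.729 to 0.0998 ± 0.244 (-4.05 ± 0.42, 1.1e-05), Hbb-bs (-3.47 ± 0.46, 8.05e-05) and Hba-a1, listed at 0 in pre-leukemic samples (0.000128). Hba-a1 and Hba-a2 are near-identical and share reads, and Hba-a2 was at 0 without pre-leukemic 1.

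The stromal list's Ly6a, the stem cell antigen Sca-1, rose (1.99 ± 0.22, 1.91e-05), though not on the TPM scale (adjusted p = 0.582, range 1.34e-06 to 0.582). Among macrophage-directed signals the 5 higher were Il10, Ifng, Tnf and Arg1, listed at 0 in healthy and at 39.9 ± 21.7, 19.5 ± 7.91, 13.4 ± 4.95 and 39.5 ± 34.7 FPKM in pre-leukemic samples (adjusted p = 3.54e-05, 3.93e-05, 0.000155 and 0.000433; 26.2 for Arg1 without pre-leukemic 3), and Cd47 (1.33 ± 0.37, 0.0144), which on the TPM scale was lower without passing. The Wnt genes Tcf7 (2.95 ± 0.82, 0.0152) and Rnf43 (adjusted p = 0.0499) and the complement regulator Cfp (3.06 ± 0.60, 0.00165) rose. The interferon gene Ifitm3 (-1.08 ± 0.36, 0.038) and the stress response genes Hyou1 (-2.17 ± 0.50, 0.00476), Calr (-0.97 ± 0.32, 0.0346) and Atf4 (-0.77 ± 0.27, 0.0463) fell. Without healthy 2 the adjusted p was above 0.05 for Cd47 (0.0996, range 0.00222 to 0.631), Tcf7 (0.227, 0.000654 to 0.227), Cfp (0.0534, 0.000352 to 0.0534) and Hyou1 (0.0582, 0.000219 to 0.0582). The calls also ended for Rnf43 without healthy 1 to 3, or pre-leukemic 1, 2, 4 or 5, or recovered 1 to 4 (0.0504 to 0.194, range 0.00832 to 0.194), Ifitm3 without healthy 2, or pre-leukemic 2 to 4 (0.0536 to 0.357, 0.00175 to 0.357), Calr without healthy 2, or pre-leukemic 3 to 6 (0.0536 to 0.174, 0.00169 to 0.174) and Atf4 without healthy 1 or 2, or pre-leukemic 1 to 5, or recovered 2 (0.0541 to 0.278, 0.000303 to 0.278).

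The median change over all genes was 0.2. Other scalings moved it and the split of calls: by -0.14 with quantile normalization (1739 higher, 2013 lower), by -1.28 on the TPM scale (790 and 4199) and by 0.12 with libraries scaled to the same sum without immunoglobulin genes (2126 and 1669). With healthy 1 and 3 as separate libraries 2542 genes were higher and 2203 lower, and with 1 healthy sample, without healthy 2, 1716 genes passed in place of 3583.

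**Figure D2:**
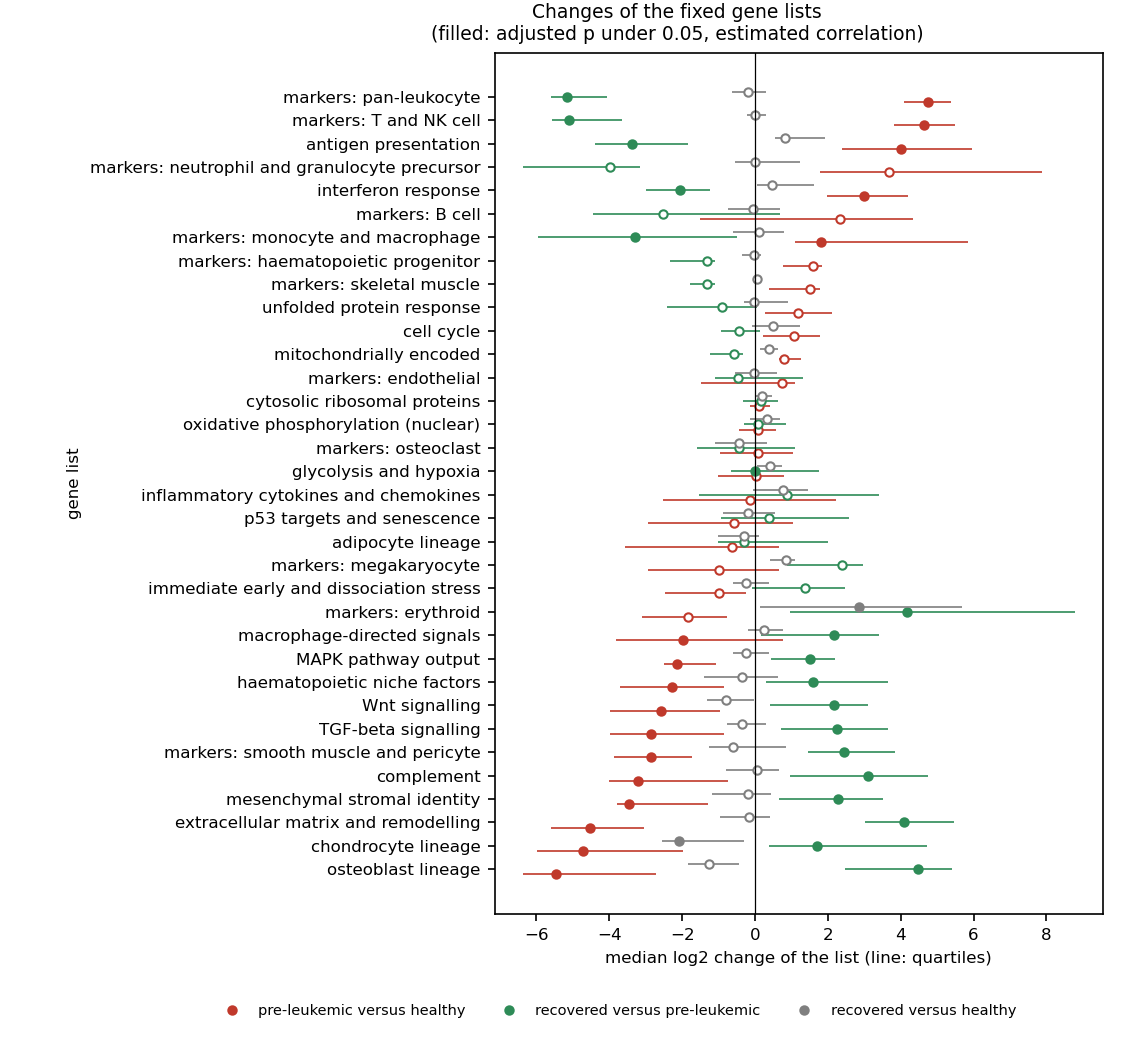
Median log2 change of each gene list (horizontal axis) in the 3 comparisons, with lines over the quartiles of its members. Filled points passed camera at an adjusted p under 0.05 with an estimated correlation. Medians of the osteoblast list were -5.45, 4.46 and -1.25, and of the pan-leukocyte markers 4.74, -5.15 and -0.2.

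The second comparison set cells sorted from MSC-treated mice against those from pre-leukemic mice. Matrix, bone and cartilage genes and globins rose, and immunoglobulin and leukocyte genes fell. Col1a1 rose from 7.71 ± 3.05 to 612 ± 138 (6.20 ± 0.33, 8.26e-09), and Prg4, the joint lubricant, rose from 98.7 ± 95.6 to 15590 ± 3710 (7.89 ± 0.61, 3.08e-07). The globins Hba-a2 from 0.0998 ± 0.244 to 922.6 ± 244 (9.70 ± 0.34, 1.24e-10) and Hbb-bs from 0.244 ± 0.395 to 530.2 ± 102 (8.77 ± 0.37, 7.47e-10) were among the largest rises, with Hba-a1 listed at 0 in pre-leukemic and 452.4 ± 120 FPKM in recovered samples (3.05e-10). Igj fell from 58550 ± 8580 to 3.47 ± 6.95 (-14.85 ± 0.60, 5.78e-10), and Ptprc fell (-5.41 ± 0.61, 9.48e-06). Means were 0 for Hba-a2 without pre-leukemic 1 and for Igj without recovered 1, and 0.11 for Hbb-bs without pre-leukemic 5. By limma, 1945 genes were higher and 3299 lower.

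Further large rises were those of Saa3, an acute phase protein, from 0.361 ± 0.885 to 542.7 ± 306 (8.65 ± 0.50, 2.01e-08), the urokinase gene Plau (8.57 ± 0.38, 1.46e-09), the monocyte attractant Ccl2 from 5.82 ± 10.4 to 775 ± 133 (7.93 ± 0.76, 1.91e-06), at 1.63 (Saa3 at 0) without pre-leukemic 6, Timp1 (8.13 ± 0.54, 7.28e-08), Mmp13 (8.04 ± 0.54, 7.77e-08), Col12a1 (7.78 ± 0.59, 2.52e-07), Clu (7.71 ± 0.56, 1.58e-07) and Chad (7.69 ± 0.50, 5.92e-08). The largest falls were immunoglobulin genes, of which 50 of 68 passed, each of them lower. Igkv5-39, Ighg2c, Ighj4, Igkv5-48, Igkv12-46, Ighv3-6, Igkv4-72 and Igkv4-57 were listed at 0 in every recovered library (adjusted p = 2.27e-14, 2.32e-11, 7.11e-12, 0.000388, 0.000256, 5.15e-10, 0.000299 and 1.43e-05). Ighg2b (-14.65 ± 0.51, 1.24e-10), Iglv1 (-13.88 ± 0.47, 1.24e-10) and Iglc2 (-13.22 ± 0.65, 3.81e-09) fell.

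Stromal identity and niche genes rose. Identity genes were 12 higher, 1 lower and 5 neither (adjusted p = 2.37e-06). Higher members were Cxcl12 (4.44 ± 0.55, 2.03e-05), Lepr (4.0 ± 0.60, 0.00012), Pdgfra (2.23 ± 0.58, 0.00738), Pdgfrb (3.45 ± 0.41, 1.49e-05), Ebf1 (3.53 ± 0.41, 1.17e-05) and Prrx1 (3.38 ± 0.42, 2.28e-05). Niche factors were 15 higher, 2 lower and 13 neither (adjusted p = 5.64e-07). Kitl (2.14 ± 0.61, 0.0129), Gas6 (5.90 ± 0.47, 3.48e-07), Igf2 (6.58 ± 0.56, 6.89e-07) and Jag1 (4.70 ± 0.45, 1.79e-06) passed. Pecam1 fell (-1.21 ± 0.45, 0.0431), a call that ended without healthy 2, or pre-leukemic 1, 2, 3, 5 or 6, or recovered 1 to 4 (0.0502 to 0.0811, range 0.00672 to 0.523). The pan-leukocyte median change was -5.15.

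Osteoblast genes were 18 higher, 1 lower and 3 neither (adjusted p = 5.73e-13). Dlx5, a homeobox gene of bone formation, rose from 0.0861 ± 0.211 to 129 ± 69.8 (6.74 ± 0.42, 4.1e-08), from 0 without pre-leukemic 1, with Spp1 (4.42 ± 0.41, 1.57e-06). Chondrocyte genes were 10 higher, 1 lower and 7 neither (adjusted p = 1.17e-06). Sox9 (5.38 ± 0.36, 7.62e-08) and Comp (6.62 ± 0.42, 5.5e-08) passed. The 52 matrix genes were 52 higher, 0 lower and 0 neither (adjusted p = 5.68e-35). They included Fn1, fibronectin, (5.63 ± 0.36, 5.8e-08), the membrane protease Mmp14 (6.66 ± 0.43, 5.68e-08) and Ctgf (6.34 ± 0.33, 6.73e-09). In the same recovered libraries Ptprc was at 0.365 to 16.4 FPKM, against 80.7 to 155 in pre-leukemic libraries.

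Signalling lists rose with them. TGF-beta genes were 16 higher, 0 lower and 10 neither (adjusted p = 7.92e-09). Id3 (4.41 ± 0.40, 1.37e-06) passed. Wnt genes were 17 higher, 3 lower and 6 neither (adjusted p = 5.49e-06). Fzd1 (3.94 ± 0.40, 3.68e-06) and Sfrp2 (4.91 ± 0.54, 6.42e-06) passed. MAPK output genes were 9 higher, 2 lower and 6 neither (adjusted p = 8.27e-05). Ier3 (4.89 ± 0.29, 2.52e-08) passed. Smooth muscle and pericyte markers were 9 higher, 0 lower and 3 neither (adjusted p = 2.16e-06). They included Tagln, an actin-binding protein, (4.40 ± 0.62, 7.21e-05) and Rgs5, listed at 0 in pre-leukemic samples (2.37e-07). Complement genes were 9 higher, 1 lower and 6 neither, 10 and 1 adjusted over the list alone (adjusted p = 5.16e-07). C1s1 (3.96 ± 0.30, 2.52e-07) passed. Macrophage-directed signals were 20 higher, 5 lower and 7 neither (adjusted p = 2.94e-07). Tnfaip6 (6.32 ± 0.44, 1.21e-07), Lgals3 (3.92 ± 0.28, 1.5e-07) and Thbs1 (3.40 ± 0.44, 3.01e-05) passed. Immediate early genes were 18 higher, 2 lower and 6 neither, 18 and 3 adjusted over the list alone (adjusted p = 5.64e-07, p = 0.0571 with estimated correlation). Egr1 (2.17 ± 0.16, 1.84e-07) passed. The pan-leukocyte median beside them was -5.15.

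Inflammatory cytokines and chemokines were 15 higher, 8 lower and 16 neither (adjusted p = 0.00477, p = 0.0608 with estimated correlation). Cxcl14 (7.45 ± 0.55, 1.9e-07) and Cxcl1 (6.63 ± 0.61, 1.37e-06) rose and Ccl5 fell (-5.46 ± 0.49, 1.14e-06). Interferon response genes were 1 higher, 25 lower and 15 neither, 1 and 29 adjusted over the list alone (adjusted p = 1.43e-06). Lower members included Psmb8 (-3.69 ± 0.34, 1.53e-06) and Mx1, listed at 0 in recovered samples (2.48e-07). Antigen presentation genes were 0 higher, 17 lower and 3 neither (adjusted p = 5.6e-08). B2m (-2.79 ± 0.14, 5.73e-09), Cd74 (-6.01 ± 0.31, 6.73e-09) and H2-K1 (-2.54 ± 0.18, 1.49e-07) passed, beside a pan-leukocyte median of -5.15 and a change in Igj of -14.85 ± 0.60. Unfolded protein response genes were 3 higher, 10 lower and 12 neither, 4 and 11 adjusted over the list alone and did not pass as a list (adjusted p = 0.163), though they did with quantile normalization (0.015, range 0.015 to 0.577). Edem1 (-4.57 ± 0.34, 2.15e-07) and Xbp1 (-3.72 ± 0.29, 3.08e-07) fell, and the 3 higher were Hyou1 (3.96 ± 0.39, 2.88e-06), Calr (1.98 ± 0.25, 2.56e-05) and Atf4 (1.61 ± 0.21, 3.49e-05).

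Pan-leukocyte markers were 0 higher, 16 lower and 0 neither (adjusted p = 1.84e-10). Rac2 (-5.52 ± 0.43, 3.19e-07), Cd48 (-5.81 ± 0.49, 6.56e-07), Lcp1 (-5.09 ± 0.44, 7.79e-07) and Fcer1g (-6.07 ± 0.52, 7.93e-07) passed. Neutrophil markers were 0 higher, 20 lower and 0 neither (adjusted p = 6.21e-07, p = 0.0761 with estimated correlation). Falls included S100a8 (-7.20 ± 0.87, 1.74e-05), Ngp (-8.62 ± 0.97, 8.62e-06) and Retnlg, listed at 0 in recovered samples (6.01e-07). Monocyte and macrophage markers were 1 higher, 7 lower and 4 neither (adjusted p = 0.00218). Ctss was lower (-7.12 ± 0.47, 6.86e-08), and Mertk, a receptor for dying cells, was listed at 0 in pre-leukemic and at 8.75 ± 13.4 FPKM in recovered samples (0.0179), or 2.14 without recovered 4. T and NK cell markers were 0 higher, 14 lower and 1 neither (adjusted p = 3.17e-09), with Cd3d and Zap70 listed at 0 in recovered samples (adjusted p = 3.47e-08 and 6.28e-08). B cell markers were 4 higher, 9 lower and 2 neither and did not pass as a list (adjusted p = 0.0871). The list passed without pre-leukemic 5 (0.0481, range 0.0177 to 0.192), without recovered 3 (0.0263), with quantile normalization (0.0233) and on the TPM scale (0.0177). The 4 higher were Igll1 and Vpreb2, at 175.3 ± 216 and 14.6 ± 16.1 FPKM in recovered samples and listed at 0 in pre-leukemic samples (adjusted p = 1.09e-06 and 0.000301), Vpreb1 (4.55 ± 0.66, 8.26e-05) and Pax5 (1.12 ± 0.31, 0.0109). Without recovered 3, at 497 and 38.2 FPKM, the means of Igll1 and Vpreb2 were 68.1 and 6.79. Erythroid markers were 4 higher, 0 lower and 4 neither (adjusted p = 1.01e-05). The higher were the globins, with Hbb-bt (6.94 ± 0.54, 3.19e-07).

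Ly6a fell (-1.08 ± 0.18, 0.000227) but did not pass with quantile normalization and was higher, without passing, on the TPM scale (0.389, range 2.1e-05 to 0.389). In that scaling the falls of the Flt3 ligand gene Flt3l (-2.50 ± 0.34, 4.5e-05), the osteoblast factor Runx2 (-2.28 ± 0.44, 0.000885) and the GTPase gene Rhob (-1.44 ± 0.37, 0.00695) had adjusted p = 0.0609 (range 1.73e-05 to 0.0609), 0.121 (0.00033 to 0.121) and 0.989 (0.00212 to 0.989). The lower Fos (-1.20 ± 0.24, 0.00114) and Cd47 (-1.02 ± 0.29, 0.0126) turned higher without passing. Col9a3, Cfp and Rnf43 were listed at 0 in recovered samples (adjusted p = 0.0168, 1.83e-05 and 0.0115), and Ifng too (adjusted p = 2.22e-06). The call on Col9a3 ended with arrayWeights (0.144, range 0.0034 to 0.144), with quantile normalization and on the TPM scale. Il10 (-4.90 ± 0.49, 3.08e-06), Tnf (-2.85 ± 0.43, 0.000128), Arg1 (-4.05 ± 0.64, 0.000185) and Tcf7 (-2.98 ± 0.65, 0.00223) fell, while Ifitm3 rose (1.54 ± 0.28, 0.000648). The Notch ligand gene Dll4 (adjusted p = 0.0281), the phosphatase genes Dusp4 (adjusted p = 0.0453) and Dusp5 (-2.0 ± 0.63, 0.0209) and the Wnt regulator Znrf3 (-1.42 ± 0.54, 0.0483) were lower. Calls ended for Dll4 without pre-leukemic 3, or recovered 1 to 4 (0.0505 to 0.0539, range 0.00292 to 0.196), Dusp4 without healthy 2, or pre-leukemic 2 or 5, or recovered 1 to 4 (0.0635 to 0.0802, 0.00544 to 0.149), Dusp5 without recovered 3 (0.0685, 0.0106 to 0.469) and Znrf3 without healthy 2 or 3, or pre-leukemic 1, 2, 3, 5 or 6, or recovered 2 to 4 (0.0506 to 0.1, 0.0159 to 0.194).

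Over all genes the median change was -0.41. It moved by 0.36 with quantile normalization (2460 higher, 2424 lower), by 1.08 on the TPM scale (3768 and 1213) and by -0.24 with sums without immunoglobulin genes (1692 and 4095). With healthy 1 and 3 separate the counts were 2052 and 3555.

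Changes from healthy to pre-leukemic and on to recovered samples were compared. Of genes higher in pre-leukemic than healthy samples 1554 were lower in recovered than pre-leukemic samples, and 1193 of those lower were higher, where independent lists would share 467.3 and 255.8. By limma 0 genes were higher in both steps (6 unadjusted) and 3 were lower (24 unadjusted), where 275.5 and 433.8 would be shared. The 3 were Brms1l (adjusted p = 0.0443 and 0.0381), Tgs1 (0.0274 and 0.0368) and Me3 (0.00563 and 0.0211). Calls ended in the first step for Brms1l without healthy 2, or pre-leukemic 2, 3, 4 or 6 (0.0565 to 0.347, range 0.00481 to 0.347) and Tgs1 without healthy 2 (0.369, 0.00212 to 0.369). In the second they ended for Brms1l without pre-leukemic 1, 2, 5 or 6, or recovered 2 to 4 (0.0542 to 0.102, range 0.0115 to 0.476) and Tgs1 without pre-leukemic 1, 2, 3, 5 or 6, or recovered 1 or 2 (0.0554 to 0.108, 0.0144 to 0.522), and for Me3 with quantile normalization (0.725, 0.0076 to 0.725), on the TPM scale, with arrayWeights and with the replicate block. The 10 genes with the largest changes in both directions were all immunoglobulin genes, adding Igkj5 and Igkv8-30 (adjusted p = 0.000888 and 0.000803 for the fall, both listed at 0 in recovered samples) to those named above. Across genes, which are not independent replicates, the changes correlated at -0.788 (-0.797 to -0.771 over 20 splits, covariance -3.04). For this the pre-leukemic libraries were divided between the comparisons. Undivided values were -0.838 and -3.14. Simulations of unchanged groups (100) gave -0.316 and -0.13 undivided and 0 and 0 divided. The overlaps share pre-leukemic libraries, which may add to their excess. A cause confined to these, such as leukocyte RNA, could give such values, so return in MSCs was not tested.

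The third comparison asked what differed between recovered and healthy samples. Globins, Saa3 and 3 of 41 interferon response genes were higher, and 6 of 18 chondrocyte genes were lower. Hba-a1 (chromosome 11, 32283511 to 32284465) rose from 6.96 ± 0.282 to 452.4 ± 120 (5.79 ± 0.45, 3.13e-05), Hba-a2 (5.65 ± 0.45, 3.13e-05), Hbb-bs from 12.9 ± 5.77 to 530.2 ± 102 (5.30 ± 0.49, 7.4e-05) and Hbb-bt (6.11 ± 0.73, 0.000621). Saa3 (chromosome 7, 46711998 to 46715700) rose from 14.5 ± 11.3 to 542.7 ± 306 (5.20 ± 0.67, 0.00109). Ucma, at 29.2 ± 19.4 FPKM in healthy samples, was listed at 0 in recovered samples (6.94e-05), as were the bone secreted factor Ostn, at 23.6 ± 1.44 (6.03e-05), the receptor pseudogene Vmn1r-ps145, at 19.6 ± 10.9 (7.4e-05), the cartilage collagen Col9a1, at 4.08 ± 2.35 (0.00492), and the Wnt ligand Wnt16, at 11.6 ± 4.39 (0.000706). By limma, 68 genes were higher and 261 lower, and 2161 had an unadjusted p under 0.05.

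**Figure D3:**
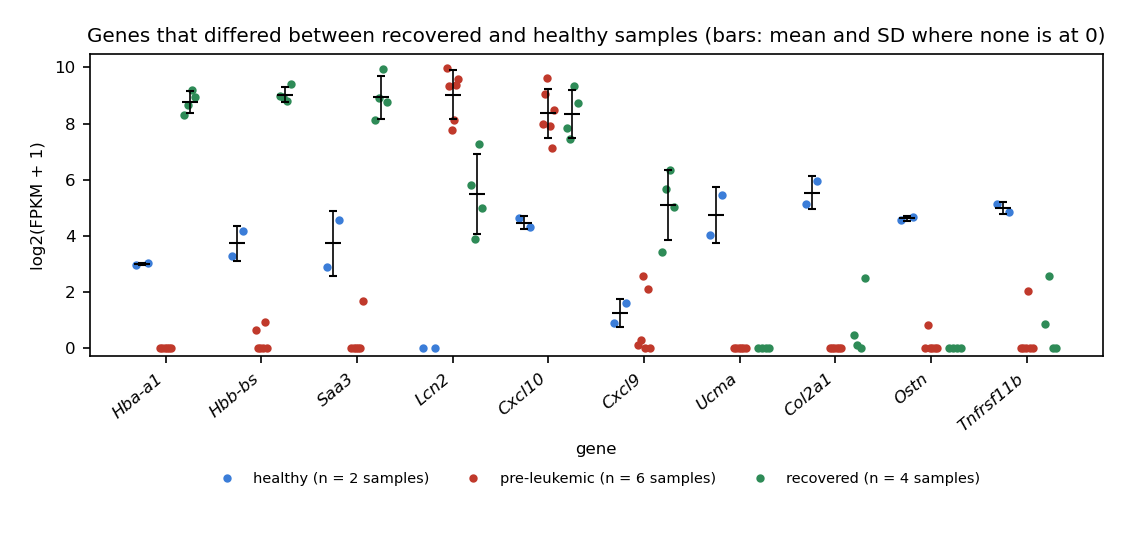
Genes that differed between recovered and healthy samples, shown in every sample of the 3 groups as log2(FPKM + 1) on the vertical axis. Points are samples, and bars give the mean and SD of that log value where no sample of the group is at 0. Hba-a1 averaged 6.96 ± 0.282 FPKM in healthy and 452.4 ± 120 in recovered samples, and Col2a1 47.3 ± 19.2 and 1.27 ± 2.24 (0.156 without recovered 4).

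Lcn2 and members of inflammatory, interferon and antigen presentation lists were higher. Lcn2, an iron-binding defence protein, was listed at 0 in healthy and averaged 62.9 ± 61.9 FPKM in recovered samples (0.00215), or 33.1 without recovered 3. Cxcl10, an interferon-induced chemokine, rose from 21.3 ± 3.42 to 367 ± 212 (3.87 ± 0.61, 0.00486), with Cxcl9 (3.87 ± 0.90, 0.0372), Cxcl5 (3.80 ± 0.74, 0.0158) and Ccl11 (4.66 ± 1.11, 0.0412). The antiviral gene Rsad2 rose (3.61 ± 0.59, 0.0058), as did Ifit1, listed at 0 in healthy samples (0.0182). Cd74 rose (2.37 ± 0.42, 0.00855) and H2-K1 rose (1.27 ± 0.24, 0.0146). Isg15 (2.92 ± 0.84, 0.0935) and H2-Q7 (2.96 ± 0.76, 0.0586), which shares reads with other H2-Q genes, did not pass, but did in 1 and 3 alternatives (ranges 0.0416 to 0.649 and 0.0111 to 0.656). Inflammatory genes were 5 higher, 0 lower and 34 neither, 6 and 0 adjusted over the list alone (adjusted p = 3.29e-05, p = 0.0506 with estimated correlation). Interferon response genes were 3 higher, 0 lower and 38 neither, 6 and 1 adjusted over the list alone (adjusted p = 5.44e-05, p = 0.0962 with estimated correlation). Antigen presentation genes were 2 higher, 0 lower and 18 neither, 9 and 0 adjusted over the list alone (adjusted p = 7.95e-07, p = 0.0506 with estimated correlation). In the same samples the pan-leukocyte markers had a median change of -0.2, but recovered 3 stood apart. Its mean log2 value was 3.87 for these markers, against 1.97 to 2.04 in the other recovered and 2.58 to 2.65 in healthy samples, and 5.07 for antigen presentation, against 3.82 to 4.42 and 3.32 to 3.47. Without recovered 3 the inflammatory, interferon and antigen presentation lists had adjusted p = 9.6e-06, 0.000138 and 6.05e-06 (ranges 6.22e-06 to 0.00142, 4.02e-06 to 0.00174 and 7.12e-08 to 1.11e-05) at the preset correlation. Without healthy 2 the adjusted p was above 0.05 for Cxcl10 (0.0981, range 0.000815 to 0.0981), Cxcl5 (0.188, 0.000688 to 0.315), Rsad2 (0.0869, 0.00111 to 0.126), Ifit1 (0.176, 0.00161 to 0.214), Cd74 (0.065, 0.00154 to 0.247) and H2-K1 (0.135, 0.00166 to 0.279). Calls also ended for Cxcl9 without healthy 2, or pre-leukemic 1 or 2, or recovered 2 to 4 (0.0504 to 0.242, range 0.00692 to 0.242) and Ccl11 without healthy 2, or pre-leukemic 1, 5 or 6, or recovered 1, 3 or 4 (0.0544 to 0.442, 0.0126 to 0.442).

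Col2a1, the main collagen of cartilage (chromosome 15, 97975602 to 98004695), fell from 47.3 ± 19.2 to 1.27 ± 2.24 (-4.76 ± 0.62, 0.00118), and Col11a1, which assembles with it, from 36.5 ± 14.1 to 2.42 ± 2.5 (-3.75 ± 0.64, 0.00729). Their recovered means were 0.156 without recovered 4 and 1.5 without recovered 1. Chondrocyte genes were 0 higher, 6 lower and 12 neither, 1 and 10 adjusted over the list alone (adjusted p = 8.66e-06). Osteoblast genes were 1 higher, 0 lower and 21 neither, 1 and 5 adjusted over the list alone (adjusted p = 0.00365, p = 0.151 with estimated correlation, fry adjusted p = 0.0175). The median change was -1.25 although the gene called, the homeobox gene Dlx3, rose from 3.29 ± 1.02 to 32.1 ± 9.27 (2.92 ± 0.48, 0.006). Phex, a bone protease, did not pass (-2.20 ± 0.56, 0.0574), but did in 5 alternatives (range 0.00644 to 0.477). Wnt genes, of which Wnt16 was the lower, were 0 higher, 1 lower and 25 neither (adjusted p = 0.023, p = 0.243 with estimated correlation, fry adjusted p = 0.0136). Without recovered 1 the list had adjusted p = 0.0794 (range 0.00888 to 0.0794). The call on Col11a1 ended without healthy 2 (0.108, range 0.00162 to 0.24), that on Col2a1 in the fit of only these groups (0.149, 9.58e-05 to 0.149) and that on Dlx3 there and with a pseudocount of 0.1 (0.0732, 0.000742 to 0.0732).

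Erythroid markers were 4 higher, 0 lower and 4 neither (adjusted p = 7.95e-07), the higher being the globins. The unfolded protein response list was 1 higher, 0 lower and 24 neither, 5 and 0 adjusted over the list alone (adjusted p = 0.0348, p = 0.338 with estimated correlation). It had a median of -0.03, a mean of 0.22 and a test pointing up. It did not pass without recovered 1, 2 or 4 (0.0553 to 0.179, range 0.0112 to 0.314). Its higher member Pdia6, a disulfide isomerase (1.32 ± 0.31, 0.0374), lost its call without healthy 2, or pre-leukemic 1, 2, 3, 5 or 6, or recovered 4 (0.0504 to 0.203, range 0.00736 to 0.306).

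Also higher were Fbxo9 (4.29 ± 0.69, 0.00518), the coagulation factor F13a1 from 4.87 ± 6.35 to 63 ± 17.6 (4.04 ± 0.71, 0.00819) and Cmtm8, listed at 0 in healthy samples (0.0454). Lower were Iglc2 (-5.13 ± 0.87, 0.00704), Tmem204 from 123 ± 7.94 to 7.9 ± 11.7 (-4.81 ± 1.16, 0.0434), Prss36, listed at 0 in recovered samples (0.0167), Tspan8 (-4.39 ± 0.67, 0.00399), the nucleoporin Nup214 (-4.38 ± 0.77, 0.00832), Dram2 (-4.27 ± 0.93, 0.0271), the osteoclast inhibitor Tnfrsf11b from 31 ± 4.84 to 1.45 ± 2.39 (-4.13 ± 0.76, 0.0115) and Fam26f (-4.08 ± 0.88, 0.0261). Recovered means were 2.12 for Tmem204 without recovered 1 and 0.269 for Tnfrsf11b without recovered 2. Without healthy 2 each of Fbxo9 (0.0865, range 0.00284 to 0.165), F13a1 (0.144, 0.00475 to 0.16), Iglc2 (0.146, 0.000222 to 0.146), Prss36 (0.297, 0.000968 to 0.297), Tspan8 (0.0653, 7.43e-05 to 0.204), Nup214 (0.161, 0.000308 to 0.238), Dram2 (0.384, 0.00845 to 0.384), Tnfrsf11b (0.104, 0.00193 to 0.202) and Fam26f (0.348, 0.00447 to 0.348) had an adjusted p above 0.05. The calls ended for Cmtm8 without healthy 2, or pre-leukemic 2 to 5, or recovered 1, 3 or 4 (0.0514 to 0.351, range 0.01 to 0.351) and Tmem204 without healthy 2, or pre-leukemic 1, 2, 3 or 5, or recovered 2 to 4 (0.0527 to 0.359, 0.00847 to 0.359) as well.

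Most stromal lists did not pass camera between recovered and healthy samples, but fry's mixed test, for changes in either direction, passed for identity (adjusted p = 0.000661), niche (3.99e-05), MAPK (0.000646) and immediate early genes (0.0408). Identity genes were 0 higher, 1 lower and 17 neither, 1 and 3 adjusted over the list alone (adjusted p = 0.791), the lower being Tnfrsf11b. Cxcl12 stood at a log2 change of 0.72 ± 0.73 (adjusted p = 0.702), Lepr at 0.29 ± 0.81 (0.935), Pdgfra at -0.99 ± 0.78 (0.588) and Pdgfrb at -1.25 ± 0.55 (0.275). Niche factors were 0 higher, 0 lower and 30 neither, 0 and 3 adjusted over the list alone (adjusted p = 0.511), with 0 higher and 7 lower unadjusted, and fry adjusted p = 0.298, and Kitl, at 0.98 ± 0.82, did not pass. Matrix genes were 0 higher, 1 lower and 51 neither, 0 and 3 adjusted over the list alone (adjusted p = 0.791). The lower was the protease inhibitor Timp3 (-2.26 ± 0.55, 0.0458), a call that ended without healthy 1 or 2, or pre-leukemic 1 to 6, or recovered 2 to 4 (0.05 to 0.33, range 0.0118 to 0.33). With quantile normalization the matrix list fell (adjusted p = 0.026, range 0.026 to 0.994). TGF-beta genes were 0 higher, 0 lower and 26 neither (adjusted p = 0.791), with 0 higher and 0 lower unadjusted, and fry adjusted p = 0.298. MAPK output genes were 0 higher, 1 lower and 16 neither, 0 and 2 adjusted over the list alone (adjusted p = 0.712). The lower was the transcription factor Etv1 (-2.72 ± 0.53, 0.0158). Immediate early genes were 0 higher, 1 lower and 25 neither, 0 and 2 adjusted over the list alone (adjusted p = 0.744). The lower was Fos (-1.50 ± 0.32, 0.0253), and the list fell under quantile normalization (0.00789, range 0.00789 to 0.972). Without healthy 2 the calls on Etv1 (0.0869, range 0.00118 to 0.242) and Fos (0.348, 0.0061 to 0.348) ended.

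Smooth muscle markers were 0 higher, 0 lower and 12 neither, 1 and 2 adjusted over the list alone (adjusted p = 0.744), with 2 higher and 2 lower unadjusted, and fry adjusted p = 0.231, but 0.000342 by the mixed test. Complement genes were 0 higher, 0 lower and 16 neither (adjusted p = 0.511), with 2 higher and 0 lower unadjusted, and fry adjusted p = 0.78. Macrophage-directed signals were 0 higher, 0 lower and 32 neither (adjusted p = 0.0621), with 3 higher and 2 lower unadjusted, and fry adjusted p = 0.0912 (0.0401 mixed), and passed without healthy 2 (0.0191, range 0.0191 to 0.587) and without pre-leukemic 6 (0.0379). Thbs1 stood at -2.16 ± 0.59 (adjusted p = 0.0725) and the prostaglandin synthase gene Ptges at 2.56 ± 0.76 (0.101), passing in 4 alternatives and in 1 (ranges 0.0185 to 0.443 and 0.0486 to 0.706). Pan-leukocyte markers were 0 higher, 0 lower and 16 neither (adjusted p = 0.962), with 0 higher and 1 lower unadjusted, and fry adjusted p = 0.845. Ptprc stood at 1.04 ± 0.82 (0.591) and Pecam1 at -0.56 ± 0.60 (0.724). Neutrophil markers, with Lcn2 the higher, were 1 higher, 0 lower and 19 neither (adjusted p = 0.465). Monocyte and macrophage markers were 0 higher, 0 lower and 12 neither (adjusted p = 0.816), with 0 higher and 1 lower unadjusted, and fry adjusted p = 0.845. B cell markers, with Iglc2 the lower, were 0 higher, 1 lower and 14 neither (adjusted p = 0.791, and 0.0448 without recovered 3, range 0.0448 to 0.99). T and NK cell markers were 0 higher, 0 lower and 15 neither (adjusted p = 0.929), with 0 higher and 2 lower unadjusted, and fry adjusted p = 0.298. The call on Iglc2 ended without healthy 2 (0.146, range 0.000222 to 0.146), and that on Lcn2 in the fit of only these groups (0.112, 0.000302 to 0.112).

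Of the 329 genes, 196 had also changed between pre-leukemic and healthy samples, where independent lists would share 89.9. Both comparisons use the healthy samples, so part of the excess may come from them. The median change over all genes was -0.08, moved by 0.2 with quantile normalization (66 higher, 145 lower), by -0.2 on the TPM scale (48 and 401) and by -0.14 with sums without immunoglobulin genes (44 and 287). With healthy 1 and 3 separate 231 genes were higher and 536 lower, and the count of 329 became 82 with 1 healthy sample, without healthy 2, and 682 without recovered 1.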

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

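The tests of leukocyte RNA and of a preparation difference and the scaling without immunoglobulin genes were chosen after the result was seen, and the other tests before. Of 380 groups of values checked for a library far from the rest of its group, 43 held one. In 21 of these every other library was at 0, which any value sets apart, and the others were 22 of 359, where chance gives about 1 in 20.

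Pre-leukemic libraries far from the rest of their group, in FPKM, were pre-leukemic 1 for Hba-a2 (0.599), Dlx5 (0.517) and Fabp4 (2.2), pre-leukemic 2 for Ostn (0.745) and Plvap (0.101), pre-leukemic 3 for Ighv3-6 (563) and Etv1 (0.473), and pre-leukemic 4 for Col12a1 (9.98), Ebf1 (0.28), Igkv8-30 (0), Tnfrsf11b (3.05), Pax5 (0.272) and Gp1bb (0.394). Pre-leukemic 5 stood apart for Igkv12-46 (2.21), Igkj5 (0), Wnt16 (1.25) and Cd47 (158), and pre-leukemic 6 for Igkv5-48 (1.71), Igkv4-72 (1.65), Saa3 (2.17) and Flt3l (24.7).

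Among recovered libraries, recovered 1 stood apart for Igj (13.9), Ngp (45.2), Iglc2 (0.793), Edem1 (8.62), Nup214 (7.49), Pparg (0.888) and Znrf3 (0.816), and recovered 2 for Cytl1 (0), Chac1 (0.269), Ndufs3 (121) and Tagln (18.1). Recovered 3 stood apart for Ighg2b (2.03), Iglv1 (2.59), Ccr2 (0.115), H2-K1 (1390), Fcer1g (2.17), Fam26f (1.25), Il10 (1.01), Atp2a1 (0.18), Tcf7 (9.49), Dusp5 (4.87) and Pf4 (0).

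The pre-leukemic libraries were rich in leukocyte and poor in stromal transcripts. Scaling alone is argued against. With sums without immunoglobulin genes the stromal identity list still had a median of -3.38 (quartiles -3.74 to -1.19). A preparation difference stays open, with mitochondrial ribosomal RNA at 0.03 to 0.09% against 0.9 to 1.23% of the sum. The median of 0.45 in 90 ribosomal and oxidative phosphorylation genes cannot decide, as scaling removes shifts common to all genes. How far RNA of leukocytes explains the stromal falls stays open, as leukocyte markers define the pattern (pan-leukocyte median 4.74) and the sort gate is not given. The falls cannot be read as regulation in MSCs. A different sort, a wrong label or a batch that follows the groups cannot be told apart from the disease state, which was not tested. The count of 3583 genes was reached by 1 of 28 splits (highest other 2) and 5244 by 1 of 100 (highest other 43). Splits mixing such unlike groups give few calls, so chance is not excluded beyond these shares.

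More genes were lower than higher in recovered versus healthy samples. Of 65 calls with a mean of at least 20 FPKM over all samples, 30.8% were lower (20 genes, exact 95% interval 19.9 to 43.4). Lower depth of the recovered libraries was to leave about 50% and other causes more. With 2 healthy but 4 recovered samples the mean favours higher calls, so depth stays open. Lower calls were 79.3%, and 68.7% with quantile normalization, 89.3% on the TPM scale and 86.7% with sums without immunoglobulin genes. No scaling tried removed the excess, but a part from scaling stays open. The 15 splits of these samples are too few for a share under 0.05, with the real count 329 and the highest other 393.

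Inflammatory, interferon and antigen presentation lists were higher in recovered than healthy samples at the preset correlation, but did not pass with an estimated one (adjusted p = 0.0506, 0.0962 and 0.0506). With quantile normalization or sums without immunoglobulin genes the lists' largest adjusted p was 0.000135 (range 6.22e-06 to 0.00142), at the preset correlation. Camera cannot see shifts of all genes, so scaling stays open. RNA of leukocytes in recovered libraries could contribute and stays open, since the pan-leukocyte median was -0.2 (quartiles -0.63 to 0.31, 0.18 without recovered 2, the highest in Ptprc, and -0.52 without recovered 3, the highest in the markers' mean) beside a smallest list median of 0.47. A change in the stromal cells themselves was not tested.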

How the results depend on the processing

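The alternatives named in the methods as added were chosen after seeing the data, and where values changed the cause was not tested. Over 330 genes and comparisons, 7440 of 7888 values kept direction and side of the threshold, 418 lost the call, 14 gained one and 16 turned. Of named genes called, 102 of 139 in pre-leukemic versus healthy, 110 of 136 in recovered versus pre-leukemic and 10 of 41 in recovered versus healthy held under each alternative, and 29, 4 and 28 lost the call without healthy 2. There 1 healthy sample was left, no lost call turned, and the median absolute log2 change went from 1.67 to 1.38, 1.42 to 1.42 and 3.83 to 3.43. With a library left out pre-leukemic versus healthy gave 1716 (without healthy 2) to 4112 genes (without recovered 3) and recovered versus pre-leukemic 4636 to 5261. Over all alternatives they gave 1716 to 5159 (only the groups compared) and 3889 (a mean of at least 5 FPKM) to 5787 (sums without immunoglobulin genes). Recovered versus healthy gave 82 to 682 with a library left out, 211 with quantile normalization, 122 with a mean of at least 5 FPKM, 103 with only the groups compared, 163 with arrayWeights and 767 with separate healthy libraries. List calls with a library left out were 23 to 24, 25 to 27 and 10 to 14, against 23, 26 and 13. They were 16, 18 and 2 with an estimated correlation and 26, 25 and 8 on the TPM scale. The correlation of -0.788 was -0.838 unsplit, -0.798 with quantile normalization, -0.773 on the TPM scale, -0.753 with a pseudocount of 0.1, -0.816 with a mean of at least 5 FPKM, -0.796 with separate healthy libraries and -0.792 to -0.763 with a library left out. On the TPM scale the log2 changes that turned in pre-leukemic versus healthy were Gpi1 -0.015, Gapdh -0.899, Cd47 -0.33, Uqcrfs1 -0.117, Ndufs3 -0.296, Ndufa4 -0.874, Rps24 -0.566 and mt-Co1 -0.583 (with quantile normalization -0.905, which passed at adjusted p = 0.0202, range 2.64e-06 to 0.177), and in recovered versus pre-leukemic Gapdh 0.739, Eno1 0.206, Fos 0.269, Cd47 0.446, Ly6a 0.388 and mt-Co1 0.095 (quantile 0.351). The replicate block gave 3700, 4527 and 303 genes and 24, 25 and 14 lists. Without it the same 13 libraries gave 4745, 5607 and 767 genes and 23, 26 and 14 lists. With group means removed, same-numbered libraries correlated at -0.019 to 0.034 (10 pairs) against -0.042 to 0.037 (44 others). The numbers were thus not taken to pair samples. Depth limits genes near the value of 3 reads on 1 kb.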

Other observations

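The values per library and the genes named for small counts were chosen after the data were seen. Variable genes of the immunoglobulin loci differed between libraries. Igkv5-39 led the kappa variable genes in all 6 pre-leukemic libraries, with 16.3 to 53.2% of their sum, while the leading heavy chain variable gene was Ighv3-6 in pre-leukemic 1, 2 and 4, Ighv8-12 in 3 and 6 and Ighv1-18 in 5.

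In pre-leukemic versus healthy samples adipocyte genes were 2 higher, 6 lower and 9 neither (adjusted p = 0.108). Plin2 (2.04 ± 0.61, 0.0235) and Pparg (2.35 ± 0.71, 0.0239) were higher and Lpl (-4.27 ± 0.74, 0.000629) and Fabp4 (-4.23 ± 0.77, 0.000943) among the lower. Cell cycle genes were 10 higher, 0 lower and 25 neither (adjusted p = 0.0138, p = 0.485 with estimated correlation), with Mcm2 (3.15 ± 0.66, 0.00248) and Cenpa (2.43 ± 0.49, 0.00218). The p53 targets were 4 higher, 9 lower and 14 neither, 5 and 9 adjusted over the list alone (adjusted p = 0.0609). The higher were Trp53inp1 (3.75 ± 0.58, 0.000283), Pmaip1 (3.84 ± 0.64, 0.000492), Tap1 (3.08 ± 0.64, 0.00251) and Ccng1 (1.60 ± 0.56, 0.0472), and Igfbp7 (-5.86 ± 0.49, 1.67e-06) fell. Nuclear oxidative phosphorylation genes were 3 higher, 1 lower and 39 neither, 0 and 0 adjusted over the list alone (adjusted p = 0.865). Uqcrfs1 (1.54 ± 0.46, 0.0217), Ndufs3 (1.35 ± 0.41, 0.0254) and Ndufa4 (0.80 ± 0.25, 0.0309) were higher and Atp5j (-0.81 ± 0.23, 0.0169) lower. The median was 0.09 with a test pointing down. Glycolysis genes were 3 higher, 7 lower and 18 neither, 4 and 7 adjusted over the list alone (adjusted p = 0.331). Gpi1 (1.63 ± 0.31, 0.00119), Gapdh (0.77 ± 0.21, 0.0152) and Eno1 (1.67 ± 0.55, 0.0361) were higher and Ndrg1 (-5.0 ± 0.52, 1e-05) and Hk2 (-3.59 ± 0.55, 0.000256) lower. The median was 0.02 and the mean -0.45. Mitochondrially encoded genes were 11 higher, 0 lower and 1 neither (adjusted p = 5.6e-06, p = 0.0795 with estimated correlation), with mt-Co1 (1.09 ± 0.13, 3.67e-05) and mt-Nd6 (2.39 ± 0.34, 0.000128). They passed neither with quantile normalization (0.83) nor on the TPM scale, where they turned (0.84, range 1.63e-06 to 0.84), and mt-Co1 fell with quantile normalization (-0.905, adjusted p = 0.0202, 2.64e-06 to 0.177). Ribosomal proteins were 9 higher, 3 lower and 35 neither (adjusted p = 0.331). Rps24 (1.11 ± 0.18, 0.000399) was higher and Rps28 (-0.96 ± 0.22, 0.00489), Rps15 (-0.60 ± 0.15, 0.00775) and Rpl35 (-0.70 ± 0.24, 0.042) lower. The list fell on the TPM scale (6.14e-07, range 6.14e-07 to 0.431). Calls ended for Plin2 without healthy 2 (0.312, range 0.00729 to 0.425), Pparg without healthy 2 (0.265, 0.00421 to 0.265), Ccng1 without healthy 1 or 2, or pre-leukemic 1 to 6, or recovered 1 (0.0523 to 0.429, 0.0068 to 0.954), Uqcrfs1 without healthy 2 (0.375, 0.0041 to 0.884), Ndufs3 without healthy 2 (0.136, 0.000809 to 0.678), Ndufa4 without healthy 2, or pre-leukemic 2, 4 or 6 (0.0522 to 0.234, 0.00826 to 0.234), Atp5j without healthy 2 (0.215, 0.000783 to 0.215), Gapdh without healthy 2 (0.163, 0.00294 to 0.163), Eno1 without healthy 2 or 3, or pre-leukemic 1, 2, 3, 5 or 6 (0.0523 to 0.458, 0.00491 to 0.942), Rps28 without healthy 2 (0.117, 4.69e-05 to 0.117), Rps15 without healthy 2 (0.0816, 0.000456 to 0.0816) and Rpl35 without healthy 2, or pre-leukemic 1, 3, 4, 5 or 6 (0.0586 to 0.222, 0.00108 to 0.222). On the TPM scale those on mt-Nd6 (0.225, range 1.67e-06 to 0.225), Tap1 (0.148, 7.58e-06 to 0.148), Cenpa (0.321, 0.000431 to 0.321), Gpi1 (0.984, 0.000127 to 0.984) and Rps24 (0.316, 3.36e-05 to 0.316) ended.

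In the same comparison megakaryocyte markers were 0 higher, 2 lower and 5 neither (adjusted p = 0.112), with Gp1bb (-3.62 ± 0.54, 0.000204) and Thbs1 lower. Endothelial markers were 1 higher, 2 lower and 11 neither (adjusted p = 0.865). Stab2 (0.00564) was higher and Plvap (-2.64 ± 0.41, 0.000251) and Ramp2 (-4.06 ± 0.93, 0.00493) lower, with a median of 0.74 and a mean of -0.09. Progenitor markers were 7 higher, 0 lower and 7 neither (adjusted p = 0.00104, p = 0.0717 with estimated correlation), with Cd27 (4.79e-07). Osteoclast markers were 1 higher, 1 lower and 4 neither (adjusted p = 0.638), Mmp9 (2.83 ± 0.95, 0.0402) higher and Ctsk (-5.22 ± 0.65, 4.65e-05) lower, with a median of 0.07 and a mean of -0.37. Skeletal muscle markers were 1 higher, 0 lower and 4 neither (adjusted p = 0.229), with Atp2a1 (0.00244) higher. Calls ended for Stab2 without healthy 2 (0.0695, range 0.000632 to 0.0695), Ramp2 without healthy 2 (0.0866, 7.62e-05 to 0.0866) and Mmp9 without healthy 2, or pre-leukemic 1 to 5 (0.0593 to 0.0876, 0.00163 to 0.363).

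In recovered versus pre-leukemic samples adipocyte genes were 6 higher, 2 lower and 9 neither, 6 and 3 adjusted over the list alone (adjusted p = 0.181), with Adipor2 (-2.88 ± 0.41, 7.91e-05) and Pparg (-2.65 ± 0.56, 0.00194) lower, a median of -0.31 and a mean of 0.55. Cell cycle genes were 1 higher, 7 lower and 27 neither, 1 and 5 adjusted over the list alone (adjusted p = 0.651), with Rrm2 (4.36 ± 0.68, 0.000164) higher and Mcm2 (-2.88 ± 0.52, 0.000525) among the lower. The p53 targets were 8 higher, 5 lower and 14 neither (adjusted p = 0.0735). Trp53inp1 (-4.22 ± 0.46, 6.75e-06), Tap1 (-4.03 ± 0.51, 2.51e-05), Pmaip1 (-3.47 ± 0.51, 9.38e-05), Sesn1 (-2.63 ± 0.39, 0.000114) and Glb1 (-1.42 ± 0.52, 0.0431) were lower. Oxidative phosphorylation genes were 11 higher, 7 lower and 25 neither, 12 and 7 adjusted over the list alone (adjusted p = 0.0309, p = 0.283 with estimated correlation), and turned with quantile normalization (0.591, range 2.9e-05 to 0.591). Glycolysis genes were 11 higher, 2 lower and 15 neither, 11 and 4 adjusted over the list alone (adjusted p = 0.0241), with Gapdh (-0.73 ± 0.17, 0.00354) and Eno1 (-1.21 ± 0.43, 0.0389) lower, but not with quantile normalization (0.102, range 0.00196 to 0.102). Mitochondrially encoded genes were 1 higher, 8 lower and 3 neither, 1 and 10 adjusted over the list alone (adjusted p = 0.00673, p = 0.269 with estimated correlation), with mt-Co1 (-1.38 ± 0.10, 2.53e-07) lower and mt-Nd3 (1.25 ± 0.30, 0.0042) higher. They turned with quantile normalization (0.921) and on the TPM scale (0.169, range 0.000301 to 0.921). Ribosomal proteins were 17 higher, 11 lower and 19 neither, 19 and 12 adjusted over the list alone (adjusted p = 0.031, p = 0.488 with estimated correlation), but not without recovered 3 (0.158) or 4 (0.0747, range 4.25e-10 to 0.83). Megakaryocyte markers were 4 higher, 0 lower and 3 neither (adjusted p = 0.00888, p = 0.0571 with estimated correlation), the higher being Gp1bb (4.96 ± 0.43, 7.93e-07), Thbs1 (3.40 ± 0.44, 3.01e-05), Pf4 (2.51 ± 0.82, 0.0256) and Itga2b (2.40 ± 0.80, 0.0287). Endothelial markers were 3 higher, 3 lower and 8 neither (adjusted p = 0.651). Ramp2 (3.96 ± 0.74, 0.000713), Plvap (1.49 ± 0.32, 0.00211) and Stab1 (3.30 ± 0.93, 0.0115) were higher and Stab2 (0.00069), Tek (-1.77 ± 0.44, 0.00548) and Pecam1 lower, with a median of -0.48 and a mean of 0.14. Progenitor markers were 1 higher, 9 lower and 4 neither, 1 and 11 adjusted over the list alone (adjusted p = 0.00254, p = 0.0761 with estimated correlation), with Cd34 (2.39 ± 0.41, 0.000391) higher and Cd27 (1.64e-08) lower. Osteoclast markers were 1 higher, 2 lower and 3 neither, 2 and 2 adjusted over the list alone (adjusted p = 0.741, median -0.43, mean 0.04), with Ctsk (5.39 ± 0.52, 2e-06) higher and Mmp9 (-3.96 ± 0.76, 0.000847) and Acp5 (-1.90 ± 0.61, 0.0238) lower. Skeletal muscle markers were 0 higher, 2 lower and 3 neither (adjusted p = 0.435), with Atp2a1 (-2.95 ± 0.49, 0.000297) and Tnnt3 (0.0197) lower. Calls ended for Glb1 without healthy 2, or pre-leukemic 1, 2, 3, 4 or 6, or recovered 2 or 4 (0.0574 to 0.119, range 0.0106 to 0.958), Eno1 without pre-leukemic 1, 2, 3, 5 or 6, or recovered 1 or 3 (0.06 to 0.105, 0.0156 to 0.792), Pf4 without pre-leukemic 1, 2, 3 or 5, or recovered 1, 2 or 4 (0.0501 to 0.0794, 0.000395 to 0.0794), Itga2b without pre-leukemic 1, 4 or 5, or recovered 2 or 3 (0.0506 to 0.0982, 0.00172 to 0.111) and Acp5 without recovered 3 or 4 (0.0522 to 0.0583, 0.00399 to 0.59). With arrayWeights those on Stab1 (0.0523, range 0.000822 to 0.0523), Tek (0.0549, 0.00228 to 0.0549), Tnnt3 (0.0789, 0.00335 to 0.0789) and mt-Nd3 (0.0764, 0.000252 to 0.0764) ended, for Tnnt3 also with the block, and on the TPM scale that on Gapdh (0.094, 0.000367 to 0.094).

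In recovered versus healthy samples cell cycle genes were 1 higher, 0 lower and 34 neither (adjusted p = 0.00303, p = 0.664 with estimated correlation), with Cenpa (2.30 ± 0.53, 0.0343). Oxidative phosphorylation genes were 1 higher, 0 lower and 42 neither (adjusted p = 0.00535, p = 0.304 with estimated correlation), with Sdhd (1.51 ± 0.34, 0.0288). Ribosomal proteins were 1 higher, 0 lower and 46 neither, 7 and 0 adjusted over the list alone (adjusted p = 1.83e-06, p = 0.291 with estimated correlation), with Rpsa (0.83 ± 0.18, 0.0261). Glycolysis genes were 0 higher, 0 lower and 28 neither (adjusted p = 0.023, p = 0.0962 with estimated correlation), with 3 higher and 0 lower unadjusted, and fry adjusted p = 0.0409. Mitochondrially encoded genes were 0 higher, 0 lower and 12 neither (adjusted p = 0.00199, p = 0.337 with estimated correlation), with 4 higher and 0 lower unadjusted, and fry adjusted p = 0.151. None of oxidative phosphorylation, glycolysis, mitochondrial and ribosomal lists passed with quantile normalization (0.93, 0.292, 0.618 and 0.587, ranges 0.00321 to 0.93, 0.0122 to 0.292, 0.000376 to 0.618 and 1.88e-09 to 0.587), and glycolysis did not without recovered 1 (0.0505). Adipocyte genes were 0 higher, 1 lower and 16 neither, 1 and 2 adjusted over the list alone (adjusted p = 0.744, 0.017 by fry's mixed test), with Adipor2 (-2.65 ± 0.56, 0.0234). The p53 targets were 0 higher, 0 lower and 27 neither (adjusted p = 0.839, 0 higher and 3 lower unadjusted, and fry adjusted p = 0.441, 0.0208 mixed). Megakaryocyte markers were 0 higher, 0 lower and 7 neither, 0 and 1 adjusted over the list alone (adjusted p = 0.356, 2 higher and 1 lower unadjusted, and fry adjusted p = 0.426). Endothelial markers were 0 higher, 0 lower and 14 neither (adjusted p = 0.856, 0 higher and 1 lower unadjusted, and fry adjusted p = 0.845, median -0.02, mean 0.04). Progenitor markers were 0 higher, 0 lower and 14 neither (adjusted p = 0.85, 1 higher and 0 lower unadjusted, and fry adjusted p = 0.827, median -0.02, test up). Osteoclast markers were 0 higher, 0 lower and 6 neither (adjusted p = 0.856, 0 higher and 0 lower unadjusted, and fry adjusted p = 0.481). Skeletal muscle markers were 0 higher, 0 lower and 5 neither (adjusted p = 0.744, 0 higher and 0 lower unadjusted, and fry adjusted p = 0.836). Calls ended for Cenpa without healthy 2, or pre-leukemic 1, or recovered 2 or 4 (0.05 to 0.345, range 0.00978 to 0.345), Sdhd without healthy 2 (0.264, 0.00722 to 0.264), Rpsa without healthy 2 (0.348, 0.00707 to 0.453) and Adipor2 without healthy 2 (0.247, 0.00299 to 0.315).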
